A study of Mus musculus with 6 samples.

How the data were processed

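The series holds bulk RNA-seq of retinas from 6 newborn mice of mixed, mostly CD-1 background, 3 controls and 3 Lhx2 conditional knockouts, each library deposited as 1 file. Per the labels' protocols, retinas were frozen, RNA was extracted with a Qiagen RNeasy kit and libraries were made with an Illumina TruSeq RNA kit. The deposited values are whole-number read counts per Ensembl gene, not normalized, with 39179 gene rows and 5 rows that name no gene in every file. Per the submitters' processing notes, STAR, HTSeq, edgeR and the GRCm38 build were used, with no versions. The strand setting of the counting is not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty. Reads aligned to several places were set apart in a row of their own and not counted on genes, which lowers the counts of near-identical paralogs. The rows that name no gene (reads outside genes, ambiguous between genes or aligned more than once) held 26.41 to 28.76% of the counts over all deposited rows. They stayed out of library sizes and tests. The row for reads not aligned held 0 in every library, so shares of all sequenced reads are not known.

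Gene symbols, coordinates and lengths were taken from GENCODE vM21, an annotation of the same GRCm38 build; 37607 of the 39179 identifiers (95.99%) matched, and the others held 0.237% of counts. Groups were taken from the sample titles and genotype labels. The series text calls the controls wild type while their labels give the floxed Lhx2 genotype without Cre. The series text gives 3 mice per group, and libraries were treated as separate animals. Pairs of libraries of one group differed by 23.0 to 532 times the chi-square expected from counting, so no pair held the same reads.

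Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group kept 16691 genes (13771 genes had 0 reads in all libraries), library sizes were scaled by TMM, and glmQLFit and glmQLFTest with default settings gave log2 fold changes (cKO minus control), 2-sided p-values and Benjamini-Hochberg adjusted p-values, with a threshold of 0.05. Standard errors were computed from the fold change and the F statistic. CPM values are scaled by TMM except for the sex-linked genes, which are scaled by all gene counts alone. The planned model had genotype and no covariate. A further model, chosen after the data were seen, had library set as a term. Sets were defined by the widest gap in the share of deposited counts ambiguous between genes, a technical measure. Its residual degrees of freedom were 3, against 4 as planned and 2 with sex, read from 4 Y-linked genes, as a further term. The common dispersion was 0.157 as planned and 0.0176 with library set.

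Before the data were examined, 27 gene lists were fixed: Notch pathway, Müller glia, late progenitor and gliogenic factors, retinal progenitor markers, cell cycle, neurogenic factors, photoreceptor precursors, cones, bipolar, amacrine, horizontal and ganglion cells, astrocytes, pigment epithelium, lens and ciliary margin, endothelium and pericytes, microglia, blood, p53 and apoptosis, gliosis, immediate early genes, BMP, hedgehog, Wnt, FGF and MAPK signalling, sex-linked genes and mitochondrially encoded genes. Some genes are in several lists. Of the sex-linked list only Xist passed the filter, so no list test was made for it. Directions were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists, and repeated with an estimated correlation. The rule for naming genes was also set then: Lhx2 and Pdgfra; up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold, with mean CPM of at least 2, a name that is not a placeholder or pseudogene, and all cKO libraries on one side of all controls; list members past the threshold; and up to 4 list members of smallest p. With library set as a term the same rule was used with the comparison made within each set. Other genes named were chosen after their values were seen.

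Alternatives were other scalings (RLE, none), other filters (none, mean CPM of at least 1), the label number as a block, leaving out each library, DESeq2 1.42.0, limma-voom and edgeR's exact test, other thresholds, and for lists fry and leaving out Lhx2 and sex-linked genes. The depth of 31483170 to 66947478 gene counts per library makes counting error small for most genes; for genes with 3 or fewer reads over all controls, ratios are given with exact 95% intervals, or against a floor of 3 reads over the control group where there were none, and these cover counting error only. Bootstrap intervals of list medians (10000 resamples) cover the spread over genes, not over animals; intervals between libraries come from each library's mean or median of the list's centred log2 CPM, fitted with the same terms. The main test was tested on simulated counts for the comparison of cKO with control, with 200 changed genes. These were drawn only from genes above a minimum mean count and changed by at most 8-fold. The recovery of genes near 0 in controls was therefore not measured. With library sets simulated (16418 genes tested), the fit with no covariate recovered 0% of 2-fold, 32% of 4-fold and 54% of 8-fold changes with 0 wrong calls, and the fit with library set recovered 48% of 1.5-fold, 86% of 2-fold, 94% of 4-fold and 98% of 8-fold changes with 16 wrong calls. With no library sets simulated and the spread of all 6 libraries (16322 genes), the planned fit recovered 2% of 2-fold, 36% of 4-fold and 76% of 8-fold changes with 5 wrong calls. On those same counts the fit with library set recovered fewer, with 0% of 2-fold, 12% of 4-fold and 58% of 8-fold changes and 4 wrong calls.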

Results

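Retinal RNA was sequenced from newborn mice at postnatal day 0.5, with 3 control animals and 3 animals lacking Lhx2 in cells with a history of Pdgfra-driven Cre. Lhx2 is a LIM homeodomain transcription factor of eye and forebrain progenitors, and Cre is a recombinase that deletes the floxed gene. The controls carried the floxed Lhx2 alleles and are called wild type elsewhere in the submitters' notes. The libraries are named by group and label number, as control 2, 3 and 4 and as conditional knockout (cKO) 1, 2 and 3. Reads counted on genes came to 43854446, 35813377 and 32698665 in controls 2, 3 and 4, and to 50960595, 66947478 and 31483170 in cKO 1, 2 and 3. The comparison asks which transcripts depend on Lhx2 at an age when Müller glia, the last cell type born in the retina, are about to form.

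The 6 libraries fell into 2 sets that did not follow genotype. Control 2, cKO 1 and cKO 2 (set A) had 3.13 to 3.20% of their deposited counts ambiguous between genes. The share was 2.63 to 2.69% in control 3, control 4 and cKO 3 (set B). Transcripts of the mitochondrial genome took 1.15 to 1.79% of gene counts in set A and 7.14 to 9.55% in set B, and ribosomal protein genes took 2.98 to 3.86% and 1.64 to 1.83%. The first principal component held 67.5% of the variance of log2 CPM (counts scaled to library size) and separated the sets, and 10637 genes differed between sets at adjusted p under 0.05 in edgeR's quasi-likelihood test with genotype in the model. The sets have no counterpart in the labels. Each comparison is therefore given first as planned, with no covariate, and then with library set as a term, a choice made after the data were seen. Control 2 is the only control of set A, and cKO 3 is the only cKO of set B. With library set as a term, a fit without either library compares the genotypes within the other set alone.

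**Figure D1:**
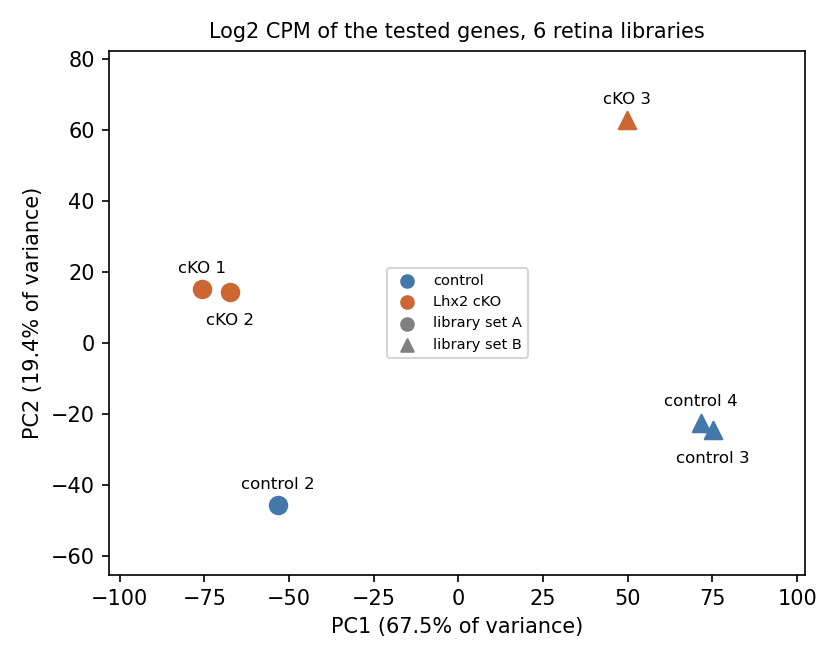
First and second principal components of log2 CPM over the tested genes, with one point per library, colour for genotype and marker shape for library set. The first component (67.5% of the variance) separates control 2, cKO 1 and cKO 2 from control 3, control 4 and cKO 3, and the second (19.4%) places each cKO library above the controls of its own set.

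Sex also differed between the groups. Xist, the RNA of the inactive X chromosome, stood at 1.28 and 3.15 CPM in controls 2 and 4 and at 2683 CPM in control 3, against 1035, 1229 and 2509 CPM in cKO 1, 2 and 3. The Y-linked gene Ddx3y reached 80.1 and 106 CPM in controls 2 and 4 and at most 0.06 CPM in the other 4 libraries. Thus 2 controls were male while 1 control and all 3 cKO mice were female. In set A the only control was male and the cKO mice were female, so that set alone cannot separate genotype from sex.

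Lhx2 transcripts were slightly lower in the cKO retinas, a difference that did not pass the threshold in the planned test and passed it with library set in the model. Lhx2 (ENSMUSG00000000247; GRCm38 chromosome 2, 38339281 to 38369733, plus strand) was counted at 308 ± 79.0 CPM in controls and 254 ± 31.3 CPM in cKO (SD, n = 3 each). Single libraries gave 399, 266 and 258 CPM in controls 2, 3 and 4 and 252, 287 and 224 CPM in cKO 1, 2 and 3. The planned test gave a log2 fold change of -0.27 (SE 0.24, adjusted p = 0.817, edgeR). With library set as a term Lhx2 fell by 0.40 on the log2 scale (SE 0.10, adjusted p = 0.0338), with -0.57 within set A and -0.22 within set B. That call was lost without control 2 (-0.22, adjusted p = 0.414), control 3 (-0.42, 0.0794), cKO 2 (-0.41, 0.0602) or cKO 3 (-0.54, 0.0727), and with sex as a further term (-0.35, 0.371). Over all alternatives with that term its adjusted p ranged from 0.000212 to 0.414. Gene-level counts include reads from exons outside any deleted part, and the deleted exons are not given in the sources used here. Pdgfra, whose promoter drove Cre, was at 30.6 ± 10.1 CPM in controls and 24.7 ± 10.3 CPM in cKO (SD, n = 3), with a log2 fold change of -0.31 (adjusted p = 0.822) as planned and -0.01 (adjusted p = 0.968) with library set.

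Crystallin transcripts, which encode the bulk proteins of the eye lens, were near 0 in every control and abundant in every cKO retina. Cryaa (GRCm38 chromosome 17, 31677807 to 31681733, plus strand) was at 1.29, 0.419 and 0.099 CPM in controls 2, 3 and 4 and at 1101, 1236 and 423 CPM in cKO 1, 2 and 3, a log2 fold change of 10.52 (SE 1.10, adjusted p = 0.0440). Cryba1 rose from 0.327 ± 0.322 to 387 ± 102 CPM (log2 fold change 10.12, SE 0.79, adjusted p = 0.0245) and Crybb3 from 0.380 ± 0.309 to 187 ± 115 CPM (log2 fold change 8.88, SE 0.97, adjusted p = 0.0440; SD, n = 3). All 12 of the genes with the largest rise by the planned rule were crystallins, namely Cryaa, Cryba1, Crygs, Cryge, Cryga, Crygc, Crygd, Crygb, Crygf, Crybb1, Crybb3 and Cryba4. Crygs and Cryga rest on 2 reads each over the 3 controls, giving ratios of 1592 (95% counting interval 440 to 13150) and 1299 (359 to 10730). The Cryg genes are close paralogs, so the split of reads among them is uncertain. Of the 21 tested members of the lens and ciliary margin list, 14 rose, 0 fell and 7 did not pass, and 19 rose when adjusted over the list alone. The list's median log2 fold change was 8.88 (camera adjusted p = 4.39e-40, and adjusted p = 0.144 with an estimated correlation).

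Over all genes, 36 of the 16691 tested rose in the cKO retinas and 0 fell in the planned edgeR test. At an unadjusted p under 0.05 the same test gave 831 higher and 461 lower genes, DESeq2 called 281 higher and 97 lower, edgeR's exact test 232 and 35, and limma-voom 25 and 0. Outside the lens list, the only called member of a fixed list was Calb1, which encodes the calcium buffer calbindin and marks horizontal cells. Calb1 rose from 3.88 ± 0.310 to 22.5 ± 1.41 CPM (log2 fold change 2.54, SE 0.19, adjusted p = 0.0245; SD, n = 3). The number of rising genes depended on single libraries, with 8 without control 2, 34 without cKO 3 and 0 without any one of control 3, control 4, cKO 1 or cKO 2, where 711 to 779 genes had an unadjusted p under 0.05. Without control 3, 3 genes fell.

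**Figure D2:**
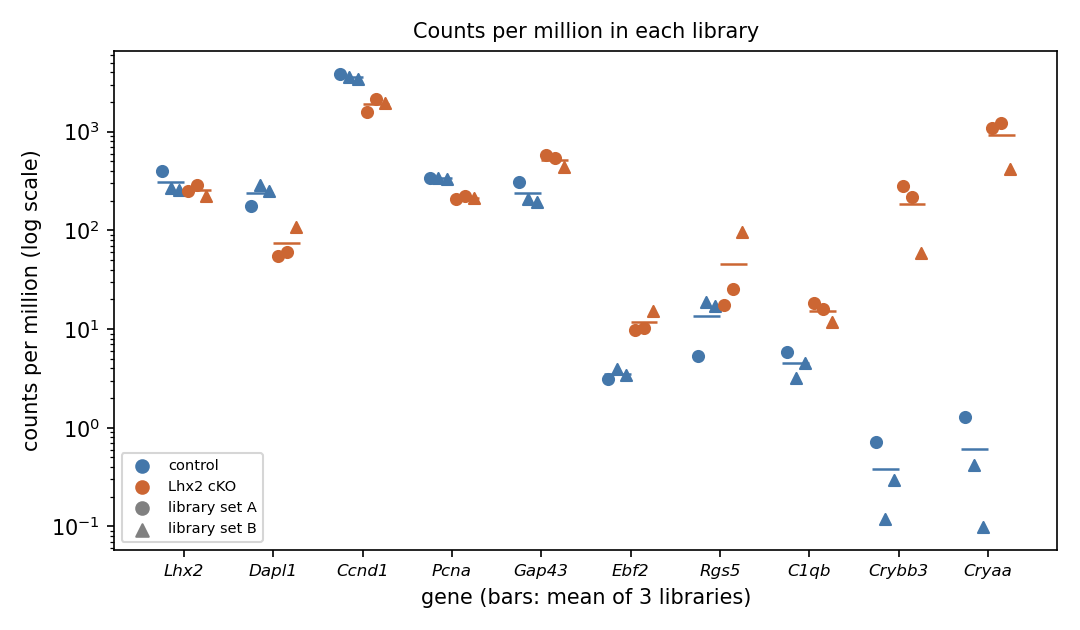
CPM of 10 genes in each library on a log axis, with blue for control and orange for Lhx2 cKO, circles for set A, triangles for set B, and bars for the mean of each group of 3. Cryaa and Crybb3 lie below 1.3 CPM in the controls and above 59 CPM in the cKO libraries, while Pcna lies between 335 and 341 CPM in controls and between 209 and 224 CPM in cKO.

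With library set as a term, 1062 genes rose and 939 fell, including all 36 genes of the planned test. By the naming rule, with its limit on mean CPM, the 12 genes with the largest rise were again the same crystallins. The 12 genes with the largest falls by the same rule were Fgf3, Hkdc1, Dio3, Slc6a2, Ass1, Lrrtm1, Ermn, Spon1, Plekhf1, Fgf15, Steap3 and Id1. Fgf3, a fibroblast growth factor, fell by 2.19 on the log2 scale (SE 0.27, adjusted p = 0.00222), from 7.71 ± 3.72 to 2.01 ± 0.546 CPM. Dio3, the deiodinase that inactivates thyroid hormone, fell by 1.76 (SE 0.20, adjusted p = 0.00143), and Ass1, a urea cycle enzyme, by 1.69 (SE 0.16, adjusted p = 0.000476). Hkdc1, a hexokinase family gene, fell from 163 to 56.1 CPM, by 1.84 on the log2 scale (SE 0.25, adjusted p = 0.00314). The interaction of set and genotype passed for 4 genes in edgeR. DESeq2 with the same term called 1170 higher and 1693 lower genes. Leaving out single libraries gave between 310 (without cKO 3) and 2707 (without cKO 1) genes, with 720 without control 2, 997 without control 3 and 1268 without control 4, and adding sex as a further term left 236 genes (173 higher, 63 lower).

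Retinal progenitor genes were lower in the cKO retinas. Of the 20 tested members of the progenitor list, 11 fell and 2 rose with library set as a term, and the list's median was -0.59 (camera adjusted p = 1.11e-04, and adjusted p = 0.402 with an estimated correlation). Ccnd1, the main D-type cyclin of the retina, fell from 3621 ± 238 to 1886 ± 265 CPM (-0.95, SE 0.12, adjusted p = 0.00254). Dapl1 fell by 1.47 on the log2 scale (SE 0.10), Fgf15 by 1.51 (SE 0.13), Rax by 0.75 (SE 0.10) and Six6 by 0.67 (SE 0.09). The members that rose were Sfrp2, a secreted Wnt modulator, from 66.6 ± 35.0 to 471 ± 36.0 CPM (log2 fold change 2.71, SE 0.22), and Car10 (0.36, SE 0.09). As planned, without the term, 0 members passed over all genes, 1 rose and 6 fell when adjusted over the list alone, and the median was -0.56 (camera adjusted p = 2.40e-06, and adjusted p = 0.159 with an estimated correlation). Of the late progenitor and gliogenic factors, 11 of 20 fell and 0 rose with library set (median -0.59, camera adjusted p = 7.37e-07, and adjusted p = 0.293 with an estimated correlation). Among these Id1 fell from 88.4 to 32.5 CPM (SE 0.16 on the log2 scale), Id2 by 1.25 on the log2 scale (SE 0.13), Sox8 by 1.04 (SE 0.12) and Zfp36l2 by 1.03 (SE 0.14). Adjusted over the list alone, 11 progenitor and 14 gliogenic genes fell with library set, and 5 gliogenic genes fell as planned, where its camera adjusted p was 2.08e-07 (0.144 with an estimated correlation). Without control 2 the falls came to 6 of the progenitor and 7 of the gliogenic list, and with sex as a further term to 3 and 4.

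The cell cycle list fell almost as a block with library set as a term. Of its 26 members 25 fell, 0 rose and Mki67 alone did not pass (-0.55, SE 0.16, adjusted p = 0.0644), with a median of -0.55 (camera adjusted p = 2.07e-15, and adjusted p = 0.402 with an estimated correlation). Pcna, the replication clamp, was at 339 ± 2.90 CPM in controls and 215 ± 7.81 CPM in cKO (log2 fold change -0.67, SE 0.08, adjusted p = 0.00143), with -0.66 in set A and -0.67 in set B. Mcm5, a subunit of the replicative helicase, fell by 0.78 on the log2 scale (SE 0.09) and Top2a by 0.64 (SE 0.14). All 26 fell when adjusted over the list alone. As planned, 0 members passed on either adjustment, with a median of -0.52 (camera adjusted p = 7.65e-10, and adjusted p = 0.159 with an estimated correlation). The count of falls was 8 without cKO 3, 4 without control 2, 18 without control 3 and 21 without control 4, and 1 with sex as a further term.

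Notch pathway genes moved in both directions. Of 24 members 8 fell with library set as a term, 2 rose and 14 did not pass (12 fell and 2 rose adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.00635, and adjusted p = 0.402 with an estimated correlation). Hes1, a transcriptional effector of Notch, fell by 0.82 on the log2 scale (SE 0.10), Notch1 by 0.70 (SE 0.17), and the ligand genes Dll4 by 0.77 (SE 0.11) and Dll1 by 0.57 (SE 0.08). Jag1 rose by 1.05 (SE 0.20) and Jag2 by 0.44 (SE 0.11). As planned, 0 members passed on either adjustment and the median was -0.10 (camera adjusted p = 0.153). The count of falls was 3 without control 2 or without cKO 3, 5 without control 3 and 1 with sex as a further term. The list's camera adjusted p was 0.0986 without control 2 and 0.0556 with sex, within a range of 0.00104 to 0.402 over all alternatives.

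Among other signalling lists, more genes of fibroblast growth factor (FGF) and MAPK signalling and of hedgehog signalling fell than rose with library set as a term. Of 17 FGF and MAPK genes 7 fell and 2 rose (median -0.39, camera adjusted p = 0.0127, and adjusted p = 0.426 with an estimated correlation). Etv4 fell by 1.18 on the log2 scale (SE 0.12), Etv5 by 0.88 (SE 0.11), Fgf9 by 0.86 (SE 0.10) and Spry2 by 0.45 (SE 0.09), while the receptor genes Fgfr3 (2.70, SE 0.34) and Fgfr2 (0.92, SE 0.24) rose. Of 12 hedgehog genes 6 fell and 0 rose (median -0.44, camera adjusted p = 0.00635, and adjusted p = 0.402 with an estimated correlation), among them the transcription factor Gli1 by 0.84 (SE 0.08) and the co-receptor Cdon by 0.74 (SE 0.10). Of 16 genes of bone morphogenetic protein (BMP) signalling Id1 and Id2 fell and the receptor gene Bmpr1b rose from 8.27 to 18.6 CPM (SE 0.20 on the log2 scale), with a list median of -0.35 (camera adjusted p = 0.0237, and adjusted p = 0.402 with an estimated correlation). Of 16 Wnt genes Sfrp2, Sp5 and Sfrp1 rose and Fzd5 fell (median 0.14, camera adjusted p = 0.0616). Adjusted over each list alone, 9 FGF, 6 hedgehog, 6 BMP and 2 Wnt genes fell and 3, 0, 1 and 6 rose. As planned, 0 members of these 4 lists passed over all genes, with camera adjusted p of 0.00232 (FGF), 8.75e-04 (hedgehog), 0.0194 (BMP) and 0.0720 (Wnt), and of 0.202, 0.186, 0.186 and 0.289 with an estimated correlation. Hedgehog falls came to 2 without control 2, 3 without control 3 and 1 without cKO 3 or with sex as a further term, which left 4 FGF falls, and BMP falls came to 5 without cKO 1. Without control 2 the camera adjusted p was 0.0693 for FGF, 0.224 for BMP and 0.0110 for Wnt, and without cKO 1 it was 0.0347 for Wnt.

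Müller glia genes did not move together. Of 22 tested members 3 rose, 4 fell and 15 did not pass with library set as a term (5 and 7 adjusted over the list alone), with a median of 0.00 (camera adjusted p = 0.555). Vim, an intermediate filament, rose from 280 ± 124 to 705 ± 194 CPM (log2 fold change 1.08, SE 0.09, adjusted p = 0.000370) and Clu, a secreted chaperone, from 9.51 ± 4.47 to 38.3 ± 16.7 CPM (1.84, SE 0.30, adjusted p = 0.00630). Timp3 also rose (0.97, SE 0.22). Spon1 fell by 1.59 on the log2 scale (SE 0.21), Sox8 by 1.04 (SE 0.12), the carbonic anhydrase gene Car2 by 0.81 (SE 0.11) and Glul, glutamine synthetase, by 0.52 (SE 0.09). As planned, 0 members passed over all genes, 1 rose and 2 fell adjusted over the list alone, and the median was -0.09 (camera adjusted p = 0.387). Without cKO 1, 5 members rose, and with sex as a further term 1 rose and 2 fell.

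Retinal ganglion cell genes were higher in the cKO retinas with library set as a term. Of 23 members 17 rose, 0 fell and 6 did not pass (20 rose adjusted over the list alone), with a median of 0.55 (camera adjusted p = 3.82e-13, and adjusted p = 0.269 with an estimated correlation). Gap43, a growth cone protein, rose from 239 ± 63.4 to 520 ± 73.6 CPM (log2 fold change 0.98, SE 0.09, adjusted p = 0.000464), and Ebf2 from 3.49 ± 0.402 to 11.8 ± 3.03 CPM (1.88, SE 0.16, adjusted p = 0.000324). Ebf3 rose by 1.13 (SE 0.10), Pou4f2 by 0.88 (SE 0.12) and Pou4f1 by 0.82 (SE 0.10). As planned, 0 members passed over all genes and 2 rose adjusted over the list alone, with a median of 0.47 (camera adjusted p = 2.35e-04, and adjusted p = 0.296 with an estimated correlation). The count of rises was 7 without cKO 3 and 3 with sex as a further term, and the planned median was 0.32 without control 2 (camera adjusted p = 0.121) and 0.06 without cKO 3 (camera adjusted p = 0.150).

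Neurogenic factors were mixed, with 8 of 21 lower and 3 higher with library set as a term (median -0.30, camera adjusted p = 0.0386, and adjusted p = 0.402 with an estimated correlation). Olig2, a transcription factor of neurogenic progenitors, fell by 0.75 on the log2 scale (SE 0.10), while Neurod2 rose by 1.46 (SE 0.20) and Neurod6 by 2.54 (SE 0.30). The falls came to 3 without control 3, control 4 or cKO 3, to 2 without control 2 and to 1 with sex as a further term, and the list's camera adjusted p was 0.255 without control 2 and 0.0517 without control 3. Of 23 photoreceptor precursor genes Rxrg rose (0.69, SE 0.12), Otx2 (-0.45, SE 0.11) and Prdm1 (-0.48, SE 0.12) fell, and 20 did not pass (median 0.00, camera adjusted p = 0.795). However, the list's median was -0.32 without control 2, from set B alone, and 0.32 without cKO 3, from set A alone. Rxrg alone rose among 12 cone genes (median 0.39, camera adjusted p = 0.0229, and adjusted p = 0.402 with an estimated correlation), a list at 0.490 without control 2 and 0.302 with sex as a further term. Among 20 amacrine genes Neurod2, Neurod6 and Calb2 rose and Sox2 and Ptf1a fell (median -0.04, mean 0.21), among 11 horizontal cell genes Calb1 and Nefm rose (median 0.15), and among 13 bipolar genes 3 rose and 2 fell (median 0.13), with camera adjusted p of 0.709, 0.237 and 0.445. Adjusted over each list alone, 3 neurogenic, 1 photoreceptor, 4 cone, 7 amacrine, 3 horizontal and 3 bipolar genes rose, and 10, 2, 0, 3, 0 and 2 fell. As planned, the camera adjusted p of these 6 lists was 0.0720, 0.951, 0.0422, 0.626, 0.507 and 0.507, and that of the cone list was 0.202 with an estimated correlation. The planned cone call was also lost with no scaling (camera adjusted p = 0.059) or no filter (0.0684), and without control 2 (0.293), cKO 1 (0.0778) or cKO 3 (0.0514).

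**Figure D3:**
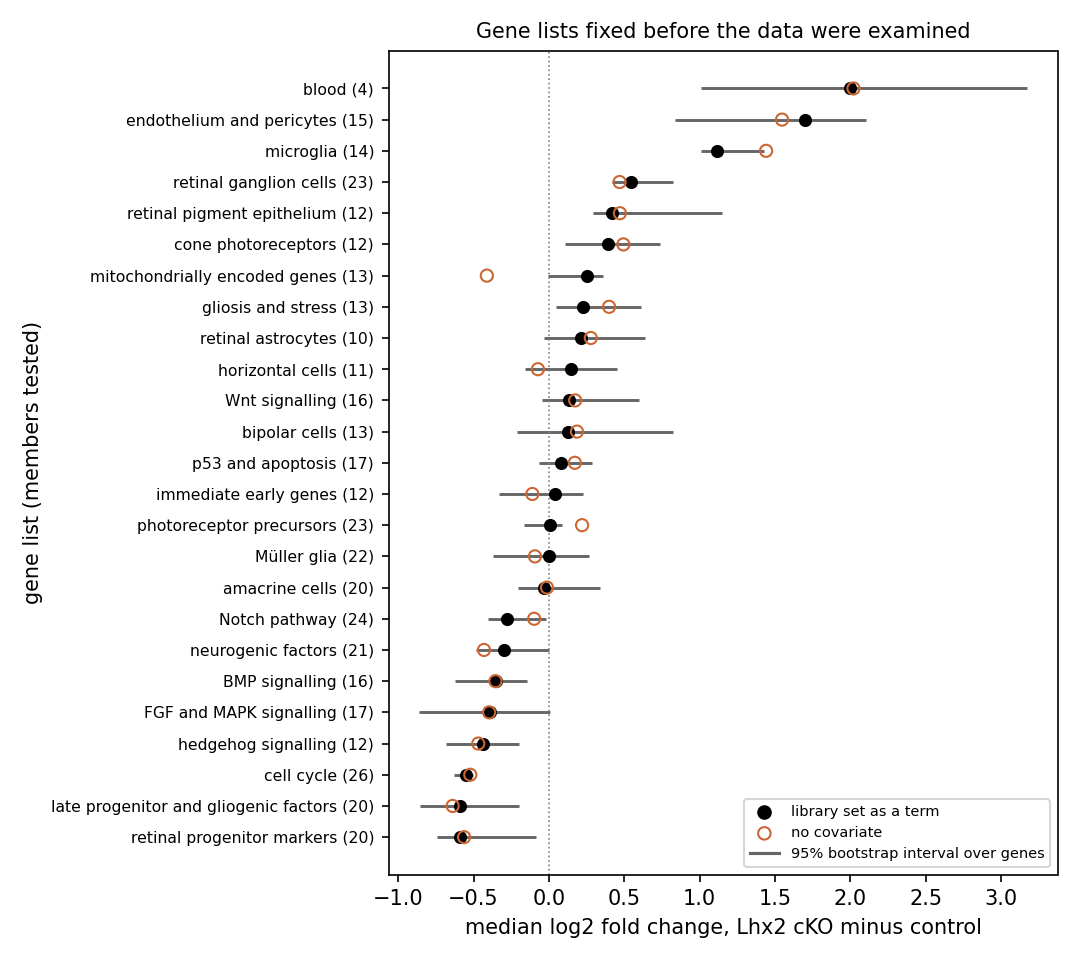
Median log2 fold change of the fixed gene lists, Lhx2 cKO minus control, with filled points for the fit with library set, open points for the fit with no covariate and lines for 95% bootstrap intervals over the genes of a list. Progenitor (-0.59) and cell cycle (-0.55) medians lie at the bottom and vessel (1.70) and blood medians at the top; the lens list (8.35 with library set) is left out because of its scale.

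Transcripts of vessels and microglia were higher in the cKO retinas, as the lens transcripts were. Of 15 endothelial and pericyte genes 12 rose and Kdr fell with library set as a term (median 1.70, camera adjusted p = 2.21e-06, and adjusted p = 0.402 with an estimated correlation). The pericyte gene Rgs5 rose by 2.24 on the log2 scale (SE 0.16) from 13.6 ± 7.26 to 46.0 ± 42.8 CPM, the endothelial cadherin gene Cdh5 by 2.13 (SE 0.27), Pecam1 by 1.70 (SE 0.27) and the basement membrane collagen gene Col4a1 by 1.17 (SE 0.18). Kdr, a receptor of vascular endothelial growth factor that retinal progenitors also express, fell by 0.71 (SE 0.14) from 617 to 341 CPM. Of 14 microglia genes 11 rose and 0 fell (median 1.11, camera adjusted p = 1.35e-08, and adjusted p = 0.269 with an estimated correlation), with C1qb at 4.54 ± 1.35 and 15.4 ± 3.38 CPM (log2 fold change 1.57, SE 0.16) and Cx3cr1 up by 1.28 (SE 0.16). Of the 4 blood genes that the filter kept the globin genes Hba-a1 (2.21, SE 0.53) and Hbb-bt (3.17, SE 0.61) rose (mean of the list 2.04, camera adjusted p = 0.0205, and adjusted p = 0.414 with an estimated correlation). With no filter 3 of 9 blood genes rose and 1 fell (median 0.996, camera adjusted p = 0.390), against a planned median of 1.14 (camera adjusted p = 0.0755), and with mean CPM of at least 1 the camera adjusted p with library set was 0.131. Among 12 genes of the retinal pigment epithelium Trpm1 rose (2.35, SE 0.44) and Otx2, which photoreceptor precursors share, fell (median 0.42, camera adjusted p = 0.0819). Among 10 astrocyte genes Igfbp2 (0.52, SE 0.09) and Aldh1l1 (1.06, SE 0.25) rose (median 0.21, camera adjusted p = 0.0819). The lens list had 19 of 21 members higher and 0 lower with library set (median 8.35, camera adjusted p = 6.46e-26), the one list still past the threshold with an estimated correlation (adjusted p = 0.0333). Adjusted over each list alone, 12 vessel, 11 microglia, 3 blood, 1 pigment epithelium, 2 astrocyte and 19 lens genes rose, and 1 vessel and 1 pigment epithelium gene fell. As planned, 0 members of the vessel, microglia, blood, pigment epithelium and astrocyte lists passed over all genes, with camera adjusted p of 4.56e-08, 1.28e-09, 3.47e-04, 0.0721 and 0.223 (0.186, 0.186, 0.202, 0.202 and 0.335 with an estimated correlation). Without cKO 3, 2 vessel, 3 microglia and 0 blood genes rose (blood camera adjusted p = 0.0950), and with sex as a further term 3, 1 and 1. Without control 3 the camera adjusted p was 0.0487 for the pigment epithelium and 0.0385 for the astrocyte list, and without cKO 1 it was 0.0236 for the pigment epithelium list.

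Lists of stress responses moved little with library set as a term. Stat3 (0.50, SE 0.09) and Osmr (1.83, SE 0.40) rose among 13 gliosis genes (median 0.23, camera adjusted p = 0.0524), Perp rose and Aen fell among 17 p53 and apoptosis genes (median 0.08, camera adjusted p = 0.458), and Btg2 fell among 12 immediate early genes (median 0.04, camera adjusted p = 0.458). The counts were the same when adjusted over each list alone. None of the 13 mitochondrially encoded genes passed in edgeR (median 0.25, camera adjusted p = 0.530). As planned, the mitochondrial list had a median of -0.41 (camera adjusted p = 0.0319, and adjusted p = 0.639 with an estimated correlation) and the gliosis list one of 0.40 (camera adjusted p = 0.0194, and adjusted p = 0.202 with an estimated correlation). The planned mitochondrial call was lost without control 3 (median -0.115), control 4 (-0.187), cKO 1 (0.087) or cKO 2 (0.085). With library set the gliosis list's camera adjusted p was 0.0343 without control 3, 0.0163 without control 4, 0.0172 without cKO 3 and 0.0101 with sex as a further term. The mitochondrial list's was 0.0113 without control 2 and 0.0285 without cKO 1.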

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

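The fits with library set or sex as a term and all of their alternatives were chosen after the data were seen; the others were planned. In the planned comparison the total of 36 genes became 378 with DESeq2 (281 higher, 97 lower), 267 with the exact test (232, 35), 0 at adjusted p under 0.01, 66 at 0.1 (64, 2) and 2001 with library set (1062, 939). The cause of the differences between tools was not tested. It stayed within 1.5 times under other scalings and filters and with limma-voom. Leaving out single libraries gave 0 to 36 genes, with 0 to 34 higher and 0 to 3 lower. The label numbers 2 and 3 occur in both groups, but nothing says that a number marks a litter, and number 2 lies in set A and number 3 in set B. With that number as a replicate block, 2040 genes passed (1007 higher, 1033 lower), Lhx2 gave -0.36, the Notch median was -0.22 (adjusted p = 0.0234) and the mitochondrial list turned to 0.23; deviations of same-numbered libraries correlated at 0.77 and 0.67 across genes.

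With library set as a term, the 2001 genes became 3063 with no filter (1592 lower), 660 at adjusted p under 0.01 (379, 281), 550 with an absolute log2 fold change of at least 1 (461, 89), 236 with sex as a further term (173, 63; 216 shared with the 2001) and 310 to 2707 without single libraries (176 to 1371 higher, 134 to 1336 lower). Falls alone moved to 1425 at adjusted p under 0.1 and 1693 with DESeq2. RLE scaling gave 949 higher and 1214 lower genes and no scaling 1252 and 800. DESeq2 shared 1968 of the 2001 calls and limma-voom 1845.

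Lhx2 passed only with the set term (-0.40) or the block (-0.36), and with the set term not with sex added (-0.35); without single libraries it ranged from -0.39 to -0.04 as planned and from -0.54 to -0.22 with the set term. The Notch list passed with the set term (-0.28) and not with sex added (-0.16) or an estimated correlation (-0.28); its median without single libraries was -0.230 to 0.056 as planned, where 3 of the 6 fits passed, and -0.31 to -0.27 with the set term. The progenitor list lost its call with an estimated correlation in both fits (-0.56 and -0.59) and kept it without any one library (-0.67 to -0.48 and -0.68 to -0.44). The Müller glia list passed in none of the planned fits. Of the other lists 13 passed as planned, 0 with an estimated correlation, 8 with fry and 8 to 14 without single libraries; with the set term 12 passed, 1 with an estimated correlation, 8 with fry, 10 with mean CPM of at least 1 and 11 to 15 without single libraries. With fry and the set term the vessel, blood, BMP, FGF, cone and neurogenic lists lost their calls. The mitochondrial list, lower as planned, turned to 0.25 with the set term. The photoreceptor list, near 0 with that term, had a median of -0.323 without control 2, where the difference comes from set B alone. Its median was 0.319 without cKO 3, where the difference comes from set A alone. The sets thus differed in direction for that list, and in set A genotype cannot be separated from sex. In 15 cases an uncalled list changed direction. No call of a single named gene reversed under any alternative. Of 135 single genes followed across the alternatives and past the threshold with the set term, 132 kept their call with limma-voom, 69 with sex added and 78 without cKO 3. Of 15 as planned, 5 kept it with limma-voom, 4 without control 2, 15 without cKO 3 and 0 without any one of the other libraries. With no scaling the median of all genes stood at 0.12 as planned, against 0.02 with TMM. Sex and the block leave 2 and 1 residual degrees of freedom. With the set term, leaving out control 2 leaves set A with no control, and leaving out cKO 3 leaves set B with no cKO. The difference then comes from the other set alone, where 1 library stands for a genotype and is assumed to vary like the others.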

Other observations

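The forebrain factors, brain transcripts, cilia, hypoxia and lens fibre lists below, and the tests on lens genes, connective tissue, retinal share, brain transcripts, sex over the listed forebrain factors, intervals between libraries and splits of the 6 libraries, were chosen only after the results were seen. Among 44 listed transcription factors that pattern the embryonic forebrain and hypothalamus, several rose in the cKO retinas. The expression filter keeps a gene near 0 in controls only where it is higher in cKO, so the list was also fitted with no filter. With library set 21 of the 44 then rose, 0 fell and 23 did not pass (median 1.87), against 18 of the 27 that the filter kept (median 2.39). Otp, a factor of hypothalamic neurons, went from 0.076 to 8.83 CPM (log2 fold change 7.15, SE 0.42), Sox1 from 1.51 to 15.5 CPM (3.89, SE 0.24) and Nhlh1 from 3.26 to 20.2 CPM (2.73, SE 0.14). Lhx5 rose by 2.39 (SE 0.24) and Tbr1 by 1.79 (SE 0.19). Uncx had 2 reads over the 3 controls and 425 over the 3 cKO libraries, a ratio of 160 (95% counting interval 44.0 to 1324). Helt had 0 reads in the controls and was at least 69.7-fold higher in cKO, and Sim1 at least 37.1-fold higher, against a floor of 3 reads over the group.

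Other genes rose in all cKO libraries by the planned test, among them Cdkn1c, an inhibitor of cyclin-dependent kinases, from 56.8 to 250 CPM (log2 fold change 2.14, SE 0.22, adjusted p = 0.0440), and Mlc1, an astroglial membrane protein, from 3.31 to 25.0 CPM (2.91, SE 0.32, adjusted p = 0.0440). With library set, Prss56, a serine protease gene, rose from 14.6 to 174 CPM (3.21, SE 0.30, adjusted p = 0.000502, edgeR). Of 24 tested genes of motile cilia 8 rose and Mns1 fell (median 0.66, camera p = 0.00130, and p = 0.240 with an estimated correlation), with Cfap65 up by 3.37 (SE 0.43). With sex as a further term 4 rose. With no filter 11 of 28 rose, of which 8 kept their call with sex, and 3 fell. Of 24 hypoxia genes Pfkfb3 and Bhlhe40 rose and Cox4i2 and Ndufa4l2 fell (median 0.10), and the list as a whole did not pass in camera.

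Crystallin, vessel and microglia transcripts were higher in the cKO libraries. Connective tissue around the eye stays open: 5 collagen and matrix genes had a median of -0.10, but the interval between libraries ran from -3.55 to 3.56, with control 2 and cKO 2 both high in set A, while in set B all 5 were higher in cKO 3 than in both controls. Induction of crystallin genes alone stays open: 19 listed lens fibre genes other than crystallins had a median of 2.72 with no filter (95% bootstrap interval 1.52 to 4.95), but the interval reached 0.60 with genes at 0 in controls set to their bound. Lens tissue carried with the retina is a candidate explanation too, since 11 of the 19 rose and 1 fell, with Capn3 at 14.7 and Mip at 12.6 CPM in cKO beside Cryaa at 920 CPM, though Lim2, Dnase2b and Lgsn had at most 6 reads over the cKO libraries. Crystallins took 0.277, 0.284 and 0.0912% of counts in cKO 1, 2 and 3, and a change of cell fate in the cKO eye that brings a wider lens programme was not tested.

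Progenitor and cell cycle genes were lower and ganglion cell genes higher in the cKO libraries. A lower share of retinal tissue would lower ganglion cell genes as well, where the other tissue lacks them. Their median was 0.55 (95% bootstrap interval 0.42 to 0.82), and the interval between libraries was 0.35 to 0.83. Brain tissue carried with the retina could not be told apart, and its neurons may express many of these genes. A lower retinal share therefore stays open for that case. Sex as the whole cause is argued against by the cell cycle median of -0.60 with sex as a further term (bootstrap interval -0.68 to -0.51, between libraries -1.03 to -0.18), under the bound of -0.1 set before the result, against -0.55 without it (-0.63 to -0.50, and -0.74 to -0.35). However, 24 of the 25 calls ended as the residual degrees of freedom went from 3 to 2, the interval between libraries of the list's mean reached 0.15, and control 3 as the only female control carries the comparison. Of 10000 random lists matched on expression, GC content and length, 0% had a median as low as that of the cell cycle list. Their medians ran from -0.25 to 0.13. The matched genes were drawn singly, while the cell cycle genes vary together (estimated correlation 0.686 with library set). The 0% therefore bears on these gene properties alone and not on the spread between animals. Litter, stage of the pups and the source of the library sets were not tested.

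Sex as the whole cause of the higher forebrain factors stays open. With sex as a further term 11 of the 44 listed rose, where 10000 lists of other genes matched on expression had at most 4. However, the list was chosen after rises were seen, and the 11 lie among the 27 that the filter kept. The matched lists were not chosen that way, so they cannot settle the question. Control 3 as the only female control also carries that comparison. Other forms of this test came earlier: that set before the result used only members that rose, which the same counts had selected, and the median over all 44 with no filter was 2.33 (95% bootstrap interval 0.62 to 3.62, or from 0.44 with genes at 0 in controls at their bound). Brain tissue carried with the retina cannot be told apart from a change within the eye: with no filter 22 brain transcripts under 5 CPM in controls had a median of 0.43 (interval -0.03 to 1.32), and 4 rose and 1 fell, while of all 35 brain transcripts 10 rose, of which 4 kept their call with sex, and 1 fell. Sst (0.265 to 4.98 CPM) and Cartpt (1.11 to 10.1 CPM) were among those that rose, while Pomc and Agrp did not pass. A shift of retinal cells toward a forebrain identity may be a further explanation and was not tested.

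The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 36 genes, and 2 splits, the real one included, gave at least as many. The highest other, 9482 genes, was the split along the library sets, which points to that structure of the samples. With library set as a term the 9 assignments within the sets are also too few: the real one, the 1 with as many, gave 2001 genes, and the highest other gave 0.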
